A study of Homo sapiens with 30 samples.

How the data were processed

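Poly-A RNA of SUM190 cells was sequenced from 30 libraries in 15 groups of 2, namely parental cells in 7 groups, doxorubicin-resistant cells in 3 and paclitaxel-resistant cells in 5. Per the submitters' processing notes, reads were aligned with STAR 2.5.1b to GRCh37 (hg19) and processed with edgeR; the read counter and the annotation are not given in the sources used here. The deposited table holds 20114 gene symbols with values that the authors made as log2(CPM + 1), with CPM scaled by TMM factors. Each library's values were whole multiples of a step within a tolerance of 0.01, which gave 18443749 to 32669995 reads per library. The floor of 3 reads covers counting error only. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

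Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with a means model of 15 groups fitted to 12743 genes that had a CPM of at least 1 in at least 2 libraries. Moderated variances used a trend and robust estimation, with 15 residual degrees of freedom and a median of 8.08 prior degrees of freedom. Each gene had 1 spread for all 15 groups, so p-values do not measure the spread of only the groups compared. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 18 comparisons, of which 3 tested whether the same dose acted differently in a resistant line and in parental cells. Comparisons that share a control group are not independent of each other. Tables were handled in Python 3.11.15 with pandas 2.3.3.

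A set of 23 gene lists was tested in each comparison: JAK-STAT components, STAT3 and STAT5 targets, interferon-stimulated genes, antigen presentation, p53 targets, G2/M and mitosis, DNA replication, replication-dependent histones, drug efflux transporters, tubulins and microtubule-associated proteins, doxorubicin targets and metabolism, luminal epithelium, basal and myoepithelial cells, mesenchymal state, markers of stromal, endothelial and immune cells, NF-kB and inflammatory cytokines, cholesterol synthesis, the integrated stress response, ER chaperones, hypoxia and glycolysis, the ERBB2 amplicon, mitochondrially encoded genes, and immediate early genes. Of 506 list genes in the table, 458 passed the filter. The limma function camera compared each list with all other genes at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and fry asked whether a list moved one way. List p-values were adjusted over the 23 lists within a comparison.

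Genes were named by a rule. They are members of the lists, or belong to the 12 genes with the largest log2 fold change in each direction among called genes with a mean CPM of at least 5 in one of the groups and no overlap between the replicates of the groups; for differences of responses the overlap condition was dropped. The lists, the naming rule, the comparisons, the test and the first set of alternatives were chosen before the data were examined. These alternatives were a pseudocount of 0.25 CPM, no filter on low values, median-of-ratios scaling, replicate number as a block, a fit with only the cell lines compared, leaving out each library in turn, and the other list tests. Leaving out 1 library leaves a group with 1, which is then assumed to vary like the other groups. A voom fit to recovered reads, a correction of each library for transcript GC content and length (GENCODE v29 transcripts, found for 99.4% of tested genes) and a crossed pairing of the replicate numbers were chosen after the data were seen. Gene order along chromosomes came from an annotation of GRCh38.p14, which differs from the authors' build, and was used only for the neighbours of a gene.

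The procedure was tested on simulated data with each gene's spread pooled over the groups and with genes drawn independently of each other. For doxorubicin-resistant against parental cells it recovered 46 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold, and called 7 unchanged genes. A linear GC trend of equal size, simulated in both parental DMSO libraries, made 5416 calls for 2.5 nM paclitaxel before the correction and 0 after it. The correction fits GC content in each library, so it could hardly leave such a trend. In the real libraries the trend differed between the parental DMSO replicates, which was not simulated.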

Results

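Messenger RNA was sequenced from SUM190, an established cell line of inflammatory breast cancer, and from derivatives resistant to doxorubicin or to paclitaxel. The 30 libraries form 15 groups of 2. Drugs were added 24 h after seeding and left on for 72 h, with DMSO as the vehicle. Parental cells received paclitaxel at 2.5 or 10 nM, doxorubicin at 65 nM or 1 µM, ruxolitinib (an inhibitor of the kinases JAK1 and JAK2) at 15 µM, or ruxolitinib with 2.5 nM paclitaxel. Doxorubicin-resistant cells received doxorubicin at 350 nM or 1 µM. Paclitaxel-resistant cells received paclitaxel at 6.5 or 10 nM, ruxolitinib at 15 µM, or ruxolitinib with 6.5 nM paclitaxel. The labels give the ruxolitinib dose as 15 µM for the single agent and as 15 nM for both combinations, and the doses are printed here as labelled. Between 18443749 and 32669995 reads per library fell in genes, and a count of 0 allows up to 3 reads, which is 0.0947 to 0.163 CPM (read counts scaled by library size) depending on the library. The series concerns JAK-STAT signalling in chemotherapy resistance, so the comparisons ask how the resistant lines differ at baseline, how each line responds to its drug, and what ruxolitinib changes. Log2 fold changes are differences of log2(CPM + 1), so the added 1 makes them smaller than the log2 ratio of the CPM values where CPM is low. Values after ± are standard errors for log2 fold changes and SD over n = 2 libraries for CPM. Genes named for the size of their change had both libraries of one group beyond both of the other in every comparison of a pair of groups.

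The libraries separated by line and by the high doxorubicin dose. Parental cells in 1 µM doxorubicin had scores of 85.7 and 91.5 on the first principal component (43.6% of variance), against -29.4 to 27.7 for all other libraries. On the second (18.7%), paclitaxel-resistant libraries lay at -22.3 to -18.5 and the other parental libraries at 12.3 to 24.7. On the third (14.7%), doxorubicin-resistant libraries lay at -36.1 to -23.4. By chi-square per degree of freedom against sampling noise, replicates of the parental DMSO group differed most (38.5) and those of parental ruxolitinib least (2.24). By Pearson r of log2 values, agreement was lowest in parental cells at 1 µM doxorubicin (0.9926, against 0.994 in parental DMSO). It was highest in paclitaxel-resistant DMSO (0.9986). Across genes, which are not independent replicates, the difference between the parental DMSO libraries followed transcript GC content (Spearman rho 0.784, 1 of 33 such relations computed). The median log2 difference of the 13 mitochondrial genes, replicate 2 minus 1, was 0.906 in this group, 0.913 in parental cells at 2.5 nM paclitaxel, 0.588 at 65 nM doxorubicin and -0.503 to 0.491 in the other groups.

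**Figure D1:**
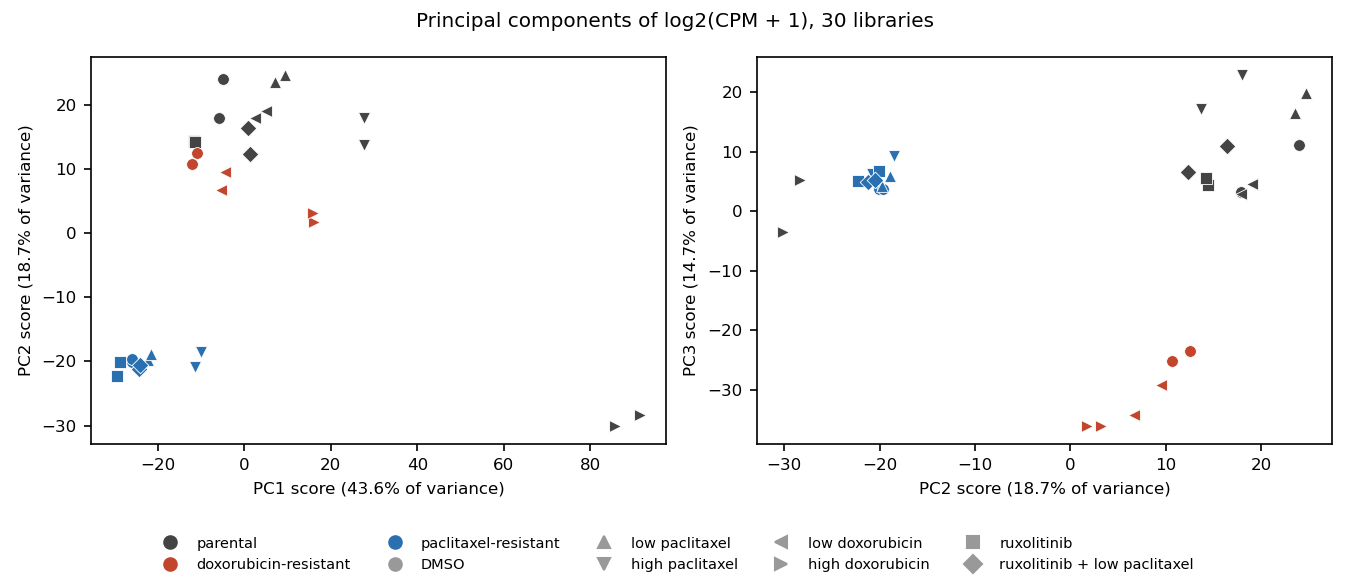
Scores of the 30 libraries on principal components 1 to 3 of log2(CPM + 1), where each point is a library, colour is the line and shape is the treatment. The 2 libraries of parental cells in 1 µM doxorubicin lie at 85.7 and 91.5 on the first component.

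Doxorubicin-resistant cells in DMSO had a raised ABCC1, which encodes an efflux pump that exports anthracyclines, and lower hypoxia genes than parental cells. ABCC1 rose by a log2 of 2.73 ± 0.09, from 81.9 ± 11.2 CPM to 548 ± 6.64 CPM (adjusted p = 2.79e-16). Of the 10 drug efflux genes measured, 4 rose and 4 fell (4 up and 4 down adjusted over the list alone, camera adjusted p = 0.689, adjusted p = 0.787 with an estimated correlation), and the list did not pass as a group. Among those that fell were the transporters ABCC2 (-1.15), ABCC5 (-0.86) and ABCC4 (-0.56) and the major vault protein gene MVP (-1.06). Of the 20 hypoxia and glycolysis genes, 0 rose and 15 fell (0 up and 15 down adjusted over the list alone, camera adjusted p = 2.17e-08, adjusted p = 0.0193 with an estimated correlation). They included the angiogenic factor VEGFA (-0.99), the glycolytic regulator PFKFB3 (-0.96) and carbonic anhydrase CA9 (-0.72). Of 23 targets of STAT3 and STAT5, 15 fell and 2 rose (2 up and 15 down adjusted over the list alone, camera adjusted p = 0.00244, adjusted p = 0.205 with an estimated correlation). The acute-phase protease inhibitor SERPINA3 changed by a log2 of -2.40 ± 0.13, HIF1A changed by -1.21, NNMT by -1.15, and TIMP1, an inhibitor of metalloproteinases, rose by 0.99. Of 30 JAK-STAT components, 7 fell and 2 rose (2 up and 7 down adjusted over the list alone, camera adjusted p = 0.101, adjusted p = 0.205 with an estimated correlation), without passing as a group. The cytokines IL6 (-1.58) and LIF (-1.22) and the receptor chains OSMR (-0.73) and IL4R (-0.86) were lower.

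In the same comparison, 7 of 19 genes for doxorubicin targets and metabolism rose and 2 fell (7 up and 3 down adjusted over the list alone, camera adjusted p = 0.00483, adjusted p = 0.205 with an estimated correlation). Those that rose included reductases of carbonyl compounds, AKR1B10 (1.59), AKR1C3 (1.35) and AKR1C2 (0.90), the quinone reductase NQO1 (1.02) and the glutathione synthesis gene GCLC (0.53). The topoisomerase genes TOP2A (0.17) and TOP2B (0.09) did not pass. Of 20 genes of the integrated stress response, 10 fell and 1 rose (1 up and 11 down adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.205 with an estimated correlation). STC2 changed by -0.86. Among the largest changes were rises in the collagen gene COL8A1 (3.65 ± 0.14), the mucin MUC5B (2.96 ± 0.30), the centrosomal genes FOPNL (2.92 ± 0.11) and NDE1 (2.87 ± 0.10), and STXBP5L (2.83 ± 0.15). The largest fall was in ANGPTL4, an inhibitor of lipoprotein lipase, at -4.96 ± 0.12, from 37.5 ± 6.42 to 0.230 ± 0.0557 CPM, a ratio of CPM that the log2(CPM + 1) scale understates. The hyaluronan receptor CD44 changed by a log2 of -3.47 ± 0.09, the surface protein CD109 changed by -3.09 ± 0.15, the connexin gene GJC1 by -2.86 ± 0.13 and MB21D1, which encodes the cytosolic DNA sensor cGAS, by -2.69 ± 0.17. In all, 3505 of 12743 genes were called, 1569 up and 1936 down, of which 165 and 172 changed by a log2 of at least 1. The count was 2280 without replicate 2 of the resistant DMSO group and 5300 after a correction for GC content and transcript length.

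ABCC1 lay within a run of neighbouring genes that were higher in doxorubicin-resistant cells, a feature chosen after its values were seen. Taking gene order from the GRCh38.p14 reference annotation, 50 of the 52 tested genes from C16orf45 to RBBP6 on chromosome 16 rose and 0 fell in the limma test, with a median log2 fold change of 0.98, whereas 12.3% of all tested genes rose. Besides ABCC1, FOPNL and NDE1, the run holds NOMO2 (2.30), which has near-identical copies. In paclitaxel-resistant cells the same 52 genes had a median log2 of -0.09 against parental cells, with 7 up and 8 down.

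**Figure D2:**
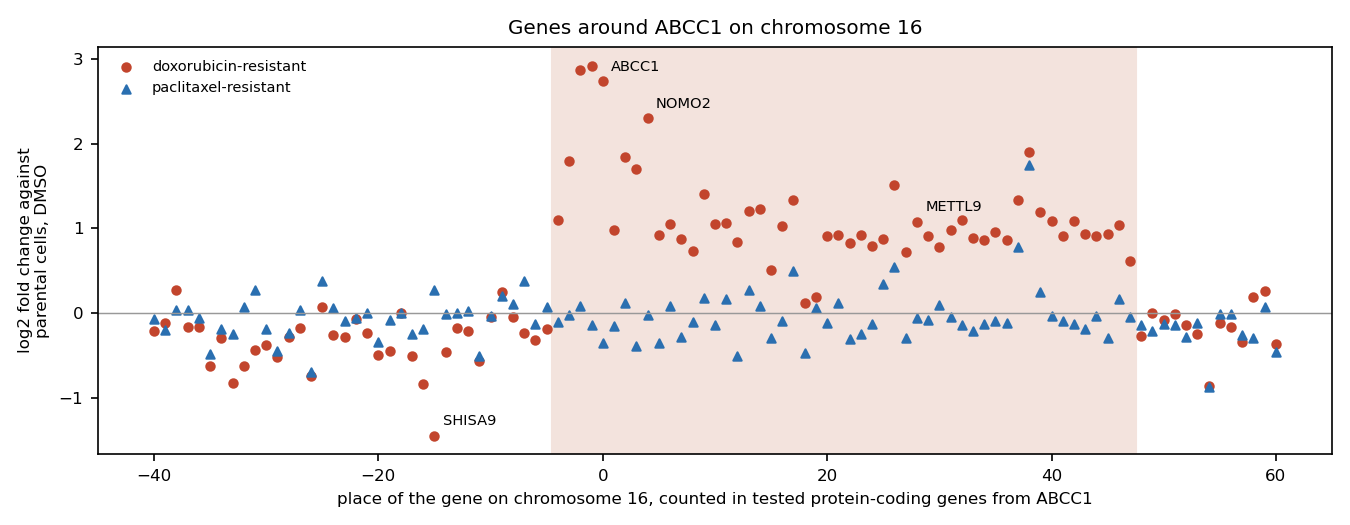
Log2 fold change against parental cells in DMSO for tested protein-coding genes around ABCC1 on chromosome 16, in gene order, where each point is a gene in a resistant line and the shaded part marks the 52 genes from C16orf45 to RBBP6. The doxorubicin-resistant points in the shaded part have a median of 0.98 and the paclitaxel-resistant points -0.09.

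Paclitaxel-resistant cells in DMSO had higher cholesterol synthesis genes and lower inflammatory and hypoxia genes than parental cells. Of 22 cholesterol synthesis genes, 17 rose and 1 fell (19 up and 1 down adjusted over the list alone, camera adjusted p = 1.25e-09, adjusted p = 0.00576 with an estimated correlation). The isomerase IDI1 rose by 1.21 ± 0.13, MSMO1 by 1.00 ± 0.13 and the synthase HMGCS1 by 0.92 ± 0.09. Of 23 NF-kB and cytokine genes, 13 fell and 1 rose (1 up and 15 down adjusted over the list alone, camera adjusted p = 3.28e-05, adjusted p = 0.00313 with an estimated correlation). The neutrophil chemokines CXCL2 (-1.99) and IL8 (-1.64) and the cytokine IL1B (-1.31) were lower, and the monocyte chemokine CCL2 (1.55) was higher. Of 20 hypoxia and glycolysis genes, 17 fell and 0 rose (0 up and 18 down adjusted over the list alone, camera adjusted p = 1.09e-08, adjusted p = 0.00642 with an estimated correlation). The vasodilator peptide gene ADM changed by -1.42, VEGFA by -0.89 and the glucose transporter SLC2A1 by -0.71. Of 14 mesenchymal genes, 8 fell and 2 rose (3 up and 8 down adjusted over the list alone, camera adjusted p = 0.000843, adjusted p = 0.0611 with an estimated correlation). Falling members were the collagen cross-linking enzyme LOX (-2.54 ± 0.18), fibronectin FN1 (-2.06 ± 0.12) and vimentin VIM (-1.44).

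IL6 changed by a log2 of -2.93 ± 0.14 in paclitaxel-resistant cells (adjusted p = 1.16e-13). Of 23 STAT3 and STAT5 targets, 14 fell and 3 rose (3 up and 14 down adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.198 with an estimated correlation). The feedback inhibitor SOCS3 changed by -1.11, SERPINA3 by -1.34 and TIMP1 by 1.65. Of 36 interferon-stimulated genes, 12 rose and 5 fell (14 up and 5 down adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.0801 with an estimated correlation). The rise reached 3.42 ± 0.22 for IFI27 and 2.58 ± 0.15 for OAS2, a sensor of double-stranded RNA, whereas the guanylate-binding gene GBP1 (-0.81) and the transcription factor IRF1 (-0.62) were lower. Of 18 tubulins and microtubule-associated proteins, 3 rose and 6 fell (3 up and 7 down adjusted over the list alone, camera adjusted p = 0.0523, adjusted p = 0.455 with an estimated correlation), without passing as a group. The beta-tubulin TUBB3 was at -1.19 and the neuronal MAP2 at 0.62. The transporter ABCC4 was lower (-1.97) and ABCG2 higher (0.70). Among the largest rises were the cancer-testis antigens MAGEA3 (3.80 ± 0.26) and MAGEA6 (3.34 ± 0.16), which share most of their sequence, SYT13 (3.68 ± 0.09), the decarboxylase DDC (3.22 ± 0.13) and the neural adhesion gene CNTN1 (3.04 ± 0.14). Among the largest falls were keratin KRT6A (-4.01 ± 0.15), which has close paralogs, C2CD4A (-3.92 ± 0.09), the calcification inhibitor MGP (-3.65 ± 0.18), the transglutaminase TGM2 (-2.80 ± 0.14) and the cornified envelope gene SPRR1B (-2.57 ± 0.19). In all, 4154 genes were called, 2078 up and 2076 down, and 225 and 214 changed by a log2 of at least 1.

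Compared directly in DMSO, the resistant lines differed in cholesterol synthesis, NF-kB and interferon-stimulated genes and in the list of doxorubicin targets and metabolism. Of 22 cholesterol synthesis genes, 19 were lower and 0 higher in doxorubicin-resistant than in paclitaxel-resistant cells (0 up and 19 down adjusted over the list alone, camera adjusted p = 1.07e-13, adjusted p = 0.00107 with an estimated correlation). MSMO1 changed by -1.65 ± 0.13 and squalene epoxidase SQLE by -1.23 ± 0.07. Of 23 NF-kB and cytokine genes, 12 were higher and 1 lower (13 up and 1 down adjusted over the list alone, camera adjusted p = 3.49e-06, adjusted p = 0.00107 with an estimated correlation). CXCL2 changed by 2.23 and the siderophore-binding LCN2 by 2.08. Of 36 interferon-stimulated genes, 16 were lower and 0 higher (0 up and 17 down adjusted over the list alone, camera adjusted p = 5.13e-05, adjusted p = 0.0263 with an estimated correlation). IFI27 changed by -2.86 and the transcription factor IRF9 by -1.27. Antigen presentation genes were lower for 9 of 18 and higher for 1 (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.00501, adjusted p = 0.465 with an estimated correlation). HLA-B changed by -1.19 and B2M by -0.93. For doxorubicin targets and metabolism, 11 of 19 were higher and 1 lower (12 up and 1 down adjusted over the list alone, camera adjusted p = 2.12e-06, adjusted p = 0.0487 with an estimated correlation). AKR1B10 changed by 2.46 ± 0.10 and heme oxygenase HMOX1 by 1.14. For genes of the ERBB2 amplicon, 6 of 10 were higher and 0 lower (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.556 with an estimated correlation). ORMDL3 changed by 0.62, while ERBB2 itself (0.15) passed only after GC and length correction. ABCC1 was higher by 3.08 ± 0.09, the fatty acid receptor CD36 by 3.45 ± 0.13 and the kinase DAPK1 by 3.25 ± 0.11. ANGPTL4 (-4.82 ± 0.12), the co-chaperone DNAJC15 (-4.16 ± 0.14), the transcription factor ETV1 (-3.87 ± 0.18) and monoamine oxidase MAOB (-3.36 ± 0.15) were lower. The limma test called 4338 genes, 1990 up and 2348 down.

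In parental cells, 10 nM paclitaxel, which stabilises microtubules, lowered genes of the cell cycle and of cholesterol synthesis and raised NF-kB, interferon-stimulated and p53 target genes. Of 30 genes of G2/M and mitosis, 30 fell (0 up and 30 down adjusted over the list alone, camera adjusted p = 2.18e-13, adjusted p = 0.0449 with an estimated correlation). The spindle gene ASPM changed by a log2 of -1.23 ± 0.16, TOP2A by -1.15 ± 0.13 and the cyclin CCNA2 by -1.01 ± 0.12. Of 30 DNA replication genes, 25 fell and 0 rose (0 up and 26 down adjusted over the list alone, camera adjusted p = 9.75e-10, adjusted p = 0.0277 with an estimated correlation). POLA1 changed by -0.97 and the ribonucleotide reductase subunit RRM2 by -0.95. Of 22 cholesterol synthesis genes, 21 fell (0 up and 21 down adjusted over the list alone, camera adjusted p = 6.84e-09, adjusted p = 0.012 with an estimated correlation). The sterol carrier STARD4 changed by -1.39 and FDFT1 by -1.14. Of 23 NF-kB and cytokine genes, 20 rose (20 up and 0 down adjusted over the list alone, camera adjusted p = 7.77e-12, adjusted p = 2.17e-05 with an estimated correlation). The apoptosis inhibitor BIRC3 changed by 2.56 ± 0.17 and IL8 by 1.84. Of 36 interferon-stimulated genes, 19 rose and 5 fell (19 up and 5 down adjusted over the list alone, camera adjusted p = 0.000687, adjusted p = 0.0449 with an estimated correlation). The antiviral RSAD2 changed by 2.26 and IFIT2 by 1.74. Of 27 p53 targets, 10 rose and 3 fell (10 up and 3 down adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.0367 with an estimated correlation). GADD45A, a growth arrest gene, changed by 2.04 and the pro-apoptotic BBC3 by 1.67. Of 16 ER chaperone genes, 12 fell and 1 rose (2 up and 12 down adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.0459 with an estimated correlation). HSP90B1 changed by -1.02. Only poly-A RNA was sequenced, so total histone mRNA was not measured. Poly-A transcripts of replication-dependent histone genes rose for 23 of 29 (25 up and 0 down adjusted over the list alone, camera adjusted p = 1.77e-09, adjusted p = 0.183 with an estimated correlation). The linker histone HIST1H1C changed by 1.88. Immediate early genes rose for 13 of 14 (13 up and 0 down adjusted over the list alone, camera adjusted p = 2.48e-09, adjusted p = 0.0573 with an estimated correlation). The stress factor ATF3 changed by 2.68 ± 0.12.

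Among the largest rises at 10 nM were those of the glycoprotein gene GPNMB (2.88 ± 0.15), the xenobiotic-metabolising CYP1A1 (2.83 ± 0.14), the deacetylase HDAC9 (2.74 ± 0.21) and PPP1R15A, which directs dephosphorylation of an initiation factor (2.60 ± 0.16). The fibrinogen chains FGB (-3.31 ± 0.12), FGA (-2.70 ± 0.19) and FGG (-2.55 ± 0.11), the growth factor binding gene IGFBP5 (-2.38 ± 0.10) and the fatty acid desaturases SCD (-1.96 ± 0.10) and FADS2 (-1.92 ± 0.16) fell. MAP1B, a microtubule-associated protein, rose by 1.65. At this dose markers of stromal, endothelial and immune cells rose for 4 of 7 and fell for 1, without passing as a group (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0798, adjusted p = 0.2 with an estimated correlation). In all, 6141 genes were called at 10 nM, 2560 up and 3581 down. At 2.5 nM, 18 of 23 NF-kB and cytokine genes rose (20 up and 0 down adjusted over the list alone, camera adjusted p = 2.89e-13, adjusted p = 8.98e-06 with an estimated correlation). BIRC3 changed by 1.23. At the same dose, 12 of 22 cholesterol synthesis genes fell (0 up and 12 down adjusted over the list alone, camera adjusted p = 1.04e-06, adjusted p = 0.0268 with an estimated correlation). STARD4 changed by -0.91. Interferon-stimulated genes rose for 18 of 36 and fell for 2 (19 up and 2 down adjusted over the list alone, camera adjusted p = 6.65e-07, adjusted p = 0.0107 with an estimated correlation). OASL changed by 1.42. Markers of stromal, endothelial and immune cells rose for 3 of 7 (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.11 with an estimated correlation), with a camera adjusted p of 0.059 without parental DMSO replicate 2, and did not pass after GC and length correction. FGB changed by a log2 of -1.58 ± 0.12, SCD changed by -1.05 ± 0.10, and CYP1A1 (1.55 ± 0.14), PPP1R15A (1.53 ± 0.16) and HMOX1 (1.22 ± 0.11) rose. The 2.5 nM contrast followed transcript GC content across genes (Spearman rho 0.641). It called 3414 genes, 1237 up and 2177 down, but 476 without replicate 1 of parental DMSO, 5172 without replicate 2, 535 without replicate 2 of the treated group and 1000 with only parental libraries in the fit.

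Paclitaxel-resistant cells at 10 nM raised NF-kB genes and lowered cholesterol synthesis genes. Of 23 NF-kB and cytokine genes, 13 rose (15 up and 0 down adjusted over the list alone, camera adjusted p = 3.64e-12, adjusted p = 1.82e-05 with an estimated correlation). IL8 changed by 1.35 ± 0.18, BIRC3 by 1.26 ± 0.17 and TNFAIP3 by 1.22 ± 0.11. Of 22 cholesterol synthesis genes, 14 fell (0 up and 17 down adjusted over the list alone, camera adjusted p = 3.64e-12, adjusted p = 0.00211 with an estimated correlation). STARD4 changed by -0.96 and the sterol sensor partner INSIG1 by -0.89. Of 19 doxorubicin targets and metabolism genes, 10 rose and 1 fell (11 up and 3 down adjusted over the list alone, camera adjusted p = 3.93e-06, adjusted p = 0.0817 with an estimated correlation). HMOX1 changed by 2.80 ± 0.11, the aldose reductase AKR1B1 by 1.16 and thioredoxin reductase TXNRD1 by 0.65. GPNMB (2.85 ± 0.15), CYP1A1 (2.27 ± 0.14), ATF3 (1.85 ± 0.12) and HIST1H1C (1.82 ± 0.12) rose. SCD (-1.50 ± 0.10), TGM2 (-1.43 ± 0.14), IGFBP5 (-1.38 ± 0.10), the matrix protein tenascin TNC (-1.36 ± 0.12) and the metallothionein MT1X (-1.21 ± 0.11) fell. In all, 1735 genes were called, 844 up and 891 down, a direction that turned without the filter on low values (908 up and 820 down). Across genes, this contrast followed transcript GC content (Spearman rho 0.219). The count was 712 and 696 without DMSO replicates 1 and 2, 1043 and 1135 without treated replicates 1 and 2, 3572 after GC and length correction and 3745 with only this line in the fit.

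At 6.5 nM, 12 genes passed in paclitaxel-resistant cells, 9 up and 3 down, and 752 had an unadjusted p under 0.05. The stress cytokine GDF15 rose by a log2 of 0.78 ± 0.09 (adjusted p = 0.000284). The tubulin list passed (1 of 18 rose, 7 up and 0 down adjusted over the list alone, camera adjusted p = 1.3e-10, adjusted p = 0.0114 with an estimated correlation), with a median log2 of 0.21. NF-kB and cytokine genes passed as a list with no member called (8 up and 0 down adjusted over the list alone, camera adjusted p = 1.78e-10, adjusted p = 4.68e-05 with an estimated correlation, median 0.21). Without DMSO replicate 1 or 2 the count was 1 and 1, and without treated replicate 1 or 2 it was 4 and 1. It was 4 without the filter on low values, 5 with voom, 107 after GC and length correction and 114 with only this line in the fit. Across genes, the 6.5 nM contrast followed transcript GC content (Spearman rho 0.283) and length (0.138).

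The response to 10 nM paclitaxel differed between the lines for 1370 genes, 875 with a higher and 495 with a lower log2 change in paclitaxel-resistant than in parental cells. The difference was positive for 22 of 30 genes of G2/M and mitosis (27 up and 0 down adjusted over the list alone, camera adjusted p = 8.52e-15, adjusted p = 0.0361 with an estimated correlation). The kinase PLK1 differed by 0.80 ± 0.14. It was positive for 15 of 30 DNA replication genes (22 up and 0 down adjusted over the list alone, camera adjusted p = 1.2e-12, adjusted p = 0.0138 with an estimated correlation). CDC45 differed by 0.75 ± 0.13. The same sign was found for 7 of 16 ER chaperones (9 up and 0 down adjusted over the list alone, camera adjusted p = 3.74e-06, adjusted p = 0.0279 with an estimated correlation). CRELD2 differed by 0.74. It was negative for 6 of 23 NF-kB and cytokine genes (0 up and 7 down adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.0023 with an estimated correlation). BIRC3 differed by -1.30 ± 0.24. For p53 targets it was negative for 2 of 27 and positive for 1 (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.00802, adjusted p = 0.0313 with an estimated correlation). BBC3 differed by -1.34 and PLK2 by 0.88. FGB differed by 2.57 ± 0.16, having changed by -3.31 in parental and by -0.73 in resistant cells, and EGR1 by -1.38 ± 0.13. The count was 639 and 727 without resistant DMSO replicates 1 and 2, 680 without resistant treated replicate 1, and 3328 after GC and length correction.

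In parental cells, 1 µM doxorubicin, a topoisomerase poison, changed most genes: 9659 were called, 4370 up and 5289 down, and 1594 and 1810 changed by a log2 of at least 1. The larger direction depended on the setting, with 6778 up and 5288 down without the filter on low values, and 4848 up and 4778 down with median-of-ratios scaling. Poly-A transcripts of replication-dependent histone genes, not their total mRNA, were measured and rose for 27 of 29 (27 up and 0 down adjusted over the list alone, camera adjusted p = 2.5e-10, adjusted p = 0.198 with an estimated correlation). HIST1H2AG changed by 4.25 ± 0.15 and HIST2H2BE by 4.00 ± 0.18. Antigen presentation genes rose for 17 of 18 (17 up and 0 down adjusted over the list alone, camera adjusted p = 3.66e-07, adjusted p = 0.0929 with an estimated correlation). HLA-B changed by 2.96 ± 0.14, HLA-E by 2.65 ± 0.11 and B2M by 1.76. Interferon-stimulated genes rose for 24 of 36 and fell for 9 (24 up and 9 down adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.0929 with an estimated correlation). IFI6 changed by 4.06 ± 0.17, ISG15 by 2.46 and OAS1 by -1.57. Cholesterol synthesis genes fell for 17 of 22 and rose for 2 (2 up and 17 down adjusted over the list alone, camera adjusted p = 0.000323, adjusted p = 0.0929 with an estimated correlation). LSS changed by -2.27 and SQLE by -2.12. Hypoxia and glycolysis genes fell for 15 of 20 and rose for 3 (3 up and 15 down adjusted over the list alone, camera adjusted p = 0.00659, adjusted p = 0.179 with an estimated correlation). SLC2A1 changed by -1.82. Of 27 p53 targets, 15 rose and 7 fell (15 up and 7 down adjusted over the list alone, camera adjusted p = 0.121, adjusted p = 0.179 with an estimated correlation), without passing as a group. GADD45A was at 3.26 ± 0.10, the cell cycle inhibitor CDKN1A at 0.76 and MDM2, which targets p53 for degradation, at -1.21. The stress genes ATF3 (4.23 ± 0.12) and PPP1R15A (4.10 ± 0.16), the pro-apoptotic PMAIP1 (3.84 ± 0.17), clusterin CLU (4.59 ± 0.16) and the actin-bundling FSCN1 (3.94 ± 0.17) rose.

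Among the largest falls at 1 µM were those of the keratinocyte caspase CASP14 (-6.26 ± 0.10), the metallothioneins MT1X (-6.10 ± 0.11) and MT2A (-4.72 ± 0.11), IGFBP5 (-5.60 ± 0.10), the oxidase NOX5 (-5.40 ± 0.09) and the acyltransferase LPCAT1 (-4.91 ± 0.07). ABCC1 changed by -0.98. Markers of stromal, endothelial and immune cells were called up for 4 of 7 and down for 1 (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.174, adjusted p = 0.365 with an estimated correlation). VWF changed by 2.47 and CD14 by 2.07. At 65 nM, 1421 genes were called in parental cells, 664 up and 757 down, and the contrast followed transcript GC content across genes (Spearman rho 0.401). The larger direction turned with median-of-ratios scaling (724 up and 665 down) and with only parental libraries (266 up and 195 down). Interferon-stimulated genes rose for 12 of 36 (13 up and 0 down adjusted over the list alone, camera adjusted p = 1.07e-07, adjusted p = 0.00835 with an estimated correlation). IFI6 changed by 1.27 ± 0.17 and OAS2 by 0.90. The stromal, endothelial and immune markers rose for 1 of 7 (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.152 with an estimated correlation). Their camera adjusted p was 0.0774 without parental DMSO replicate 2, and they did not pass without the filter on low values or after GC and length correction. The transcription corepressor HR (1.47 ± 0.18), QPRT, an enzyme of NAD synthesis (1.41 ± 0.13), and CXCL17 (1.17 ± 0.11) rose. Keratin KRT6C (-1.73 ± 0.18), the connexin gene GJB2 (-1.10 ± 0.09) and MAP2 (-1.08 ± 0.11) fell. The 65 nM count was 494 and 2527 without DMSO replicates 1 and 2, 240 without treated replicate 2, 461 with only parental libraries and 2813 after GC and length correction.

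Doxorubicin-resistant cells at 1 µM raised antigen presentation, interferon and NF-kB genes and lowered ER chaperones. Antigen presentation genes rose for 14 of 18 (15 up and 0 down adjusted over the list alone, camera adjusted p = 1.42e-07, adjusted p = 0.0413 with an estimated correlation). HLA-B changed by 1.37 ± 0.14 and the class II transactivator CIITA by 1.06. Interferon-stimulated genes rose for 21 of 36 (22 up and 0 down adjusted over the list alone, camera adjusted p = 2.91e-06, adjusted p = 0.0156 with an estimated correlation). IFI6 changed by 1.80 ± 0.17, GBP1 by 1.62 and DDX58, a sensor of viral RNA, by 1.41. NF-kB and cytokine genes rose for 15 of 23 and fell for 4 (15 up and 4 down adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.0156 with an estimated correlation). The acute-phase SAA1 changed by 1.39, the adhesion receptor ICAM1 by 1.29 and IL1B by -1.06. ER chaperones fell for 13 of 16 and rose for 1 (1 up and 13 down adjusted over the list alone, camera adjusted p = 1.64e-06, adjusted p = 0.0207 with an estimated correlation). PDIA4 changed by -1.05 and HSPA5 by -0.81. DNA replication genes rose for 18 of 30 (19 up and 1 down adjusted over the list alone, camera adjusted p = 1.64e-06, adjusted p = 0.0639 with an estimated correlation). The cell cycle factor E2F2 changed by 1.00. ABCC1 did not pass (0.02), and the transporters ABCC5 (1.03) and ABCC4 (0.78) rose. CYP1A1 (2.96 ± 0.14), the homeodomain gene HOPX (2.48 ± 0.15), keratin KRT4 (2.12 ± 0.13) and GPNMB (2.08 ± 0.15) rose, and MUC5B (-3.81 ± 0.30), MT1X (-2.29 ± 0.11), MT2A (-2.15 ± 0.11) and FGB (-1.81 ± 0.12) fell. In all, 4977 genes were called, 2438 up and 2539 down. At 350 nM, 486 were called, 304 up and 182 down: CYP1A1 (1.39 ± 0.14), MGP (1.34 ± 0.18), KRT4 (1.27 ± 0.13) and HOPX (1.25 ± 0.15) rose, and MT2A (-1.07 ± 0.11) and MT1X (-1.03 ± 0.11) fell. The 350 nM count was 130 and 143 without DMSO replicates 1 and 2, 264 and 213 without treated replicates 1 and 2, and 1681 after GC and length correction.

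The response to 1 µM doxorubicin differed between the lines for 7434 genes, 4231 with a higher and 3203 with a lower log2 change in doxorubicin-resistant than in parental cells. Without the filter on low values, 4165 were higher and 4561 lower. The difference was negative for the poly-A transcripts of 26 of 29 replication-dependent histone genes (0 up and 26 down adjusted over the list alone, camera adjusted p = 2.41e-13, adjusted p = 0.271 with an estimated correlation). HIST1H2AG differed by -3.30 ± 0.22. It was positive for 18 of 22 cholesterol synthesis genes and negative for 1 (18 up and 2 down adjusted over the list alone, camera adjusted p = 7.9e-06, adjusted p = 0.103 with an estimated correlation). LSS differed by 2.24 ± 0.18. It was negative for 12 of 18 antigen presentation genes (0 up and 12 down adjusted over the list alone, camera adjusted p = 7.81e-05, adjusted p = 0.271 with an estimated correlation). HLA-E differed by -1.98. IGFBP5 differed by 5.32 ± 0.14 and CASP14 by 4.74 ± 0.15 (CASP14 changed by -6.26 in parental and by -1.52 in resistant cells). The small GTPase gene ARL14 differed by -4.36 ± 0.18. GADD45A differed by -2.04 and ATF3 by -2.69.

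Ruxolitinib alone at 15 µM lowered STAT3 targets, interferon-stimulated, antigen presentation and mesenchymal genes in parental cells and raised genes of the integrated stress response. STAT3 and STAT5 targets fell for 13 of 23 (0 up and 14 down adjusted over the list alone, camera adjusted p = 7.8e-15, adjusted p = 0.00236 with an estimated correlation). SOCS3, a feedback inhibitor that STAT3 induces, changed by -2.26 ± 0.18 on the log2(CPM + 1) scale, which understates the ratio, from 7.48 ± 1.19 to 0.768 ± 0.0774 CPM (adjusted p = 2.81e-09), SERPINA3 by -1.85 ± 0.13 and CEBPD by -1.19 ± 0.12. JAK-STAT components fell for 13 of 30 and rose for 1 (1 up and 13 down adjusted over the list alone, camera adjusted p = 9.4e-05, adjusted p = 0.00236 with an estimated correlation). IL6 changed by -1.52 and OSMR by -1.03. Interferon-stimulated genes fell for 13 of 36 and rose for 1 (2 up and 16 down adjusted over the list alone, camera adjusted p = 4.84e-06, adjusted p = 0.00651 with an estimated correlation). GBP1 changed by -1.67 and IRF1 by -1.09. Antigen presentation genes fell for 12 of 18 (0 up and 15 down adjusted over the list alone, camera adjusted p = 3.78e-09, adjusted p = 0.0151 with an estimated correlation). The immunoproteasome subunit PSMB9 changed by -0.75. Mesenchymal genes fell for 8 of 14 (0 up and 9 down adjusted over the list alone, camera adjusted p = 1.52e-09, adjusted p = 0.00236 with an estimated correlation). TNC changed by -1.72 ± 0.12, FN1 by -1.58 ± 0.12 and the transcription factor SNAI2 by -1.02. NF-kB and cytokine genes fell for 7 of 23 (0 up and 10 down adjusted over the list alone, camera adjusted p = 0.000169, adjusted p = 0.00236 with an estimated correlation). ICAM1 changed by -1.62 and CCL2 by -1.27. Basal genes fell for 4 of 11 (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.00219, adjusted p = 0.0274 with an estimated correlation). KRT6A changed by -1.95. Genes of the integrated stress response rose for 12 of 20 and fell for 2 (13 up and 2 down adjusted over the list alone, camera adjusted p = 4.18e-08, adjusted p = 0.00236 with an estimated correlation), and the examples ASNS (1.11), PHGDH (0.92) and PSAT1 (0.86) make asparagine and serine. The serotonin receptor HTR3A (-2.49 ± 0.13), fibrinogen FGB (-2.14 ± 0.12), the tubulin TUBB3 (-1.86 ± 0.11) and DPYD, which degrades pyrimidines (-1.91 ± 0.09), fell. The ubiquitin ligase TRIM9 (1.96 ± 0.15), the receptor EPHB6 (1.57 ± 0.16) and the sulfotransferase SULT1E1 (1.30 ± 0.16) rose. In all, 1685 genes were called, 702 up and 983 down. The count was 869 and 751 without treated replicates 1 and 2, 775 with only parental libraries and 3444 after GC and length correction.

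In paclitaxel-resistant cells, 15 µM ruxolitinib lowered interferon-stimulated genes for 13 of 36 and raised 1 (2 up and 21 down adjusted over the list alone, camera adjusted p = 7.82e-09, adjusted p = 0.00207 with an estimated correlation). IRF9 changed by -1.30 ± 0.15 and PARP9 by -0.89 ± 0.08. Mesenchymal genes fell for 5 of 14 (0 up and 8 down adjusted over the list alone, camera adjusted p = 1.58e-09, adjusted p = 0.00207 with an estimated correlation). TNC changed by -1.57 ± 0.12 and SNAI2 by -1.10 ± 0.18. STAT3 and STAT5 targets fell for 8 of 23 (2 up and 8 down adjusted over the list alone, camera adjusted p = 8.03e-05, adjusted p = 0.1 with an estimated correlation). SOCS3 changed by -1.35 ± 0.18 and SERPINA3 by -0.90 ± 0.13. JAK-STAT components fell for 6 of 30 (1 up and 7 down adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.0449 with an estimated correlation). OSMR changed by -0.72. Basal genes fell for 4 of 11 (0 up and 5 down adjusted over the list alone, camera adjusted p = 0.000414, adjusted p = 0.0163 with an estimated correlation). KRT6A changed by -2.42 ± 0.15. Genes of the integrated stress response rose for 9 of 20 (11 up and 1 down adjusted over the list alone, camera adjusted p = 9.5e-09, adjusted p = 0.00207 with an estimated correlation). DDIT4 changed by 0.61, PHGDH by 0.59 and ASNS by 0.58. CCL2 (-1.73 ± 0.19), keratin KRT16 (-1.34 ± 0.12) and TUBB3 (-1.14 ± 0.11) fell, and the nuclear receptor NR4A1 (1.46 ± 0.16), the sodium channel subunits SCNN1B (1.22 ± 0.12) and SCNN1G (1.13 ± 0.12) and the secreted PIP (1.21 ± 0.16) rose. In all, 882 genes were called, 364 up and 518 down. Across genes, this contrast followed transcript GC content (Spearman rho 0.295). The count was 360 and 358 without DMSO replicates 1 and 2, 369 and 407 without treated replicates 1 and 2, 1914 after GC and length correction and 2102 with only this line.

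The ruxolitinib response differed between the lines for 52 genes, 38 with a higher and 14 with a lower log2 change in paclitaxel-resistant than in parental cells. Differences were positive for fibrinogen FGA (2.01 ± 0.27), the acute-phase ORM1 (1.87 ± 0.17), FN1 (1.33 ± 0.17) and GBP1 (1.32 ± 0.17), and negative for IGFBP5 (-1.62 ± 0.14) and the matrix gene MATN2 (-0.85 ± 0.12). STAT3 and STAT5 targets differed as a list, with 1 member called (8 up and 0 down adjusted over the list alone, camera adjusted p = 3.26e-12, adjusted p = 0.00882 with an estimated correlation) and a median log2 of 0.33, and NF-kB genes likewise (4 up and 0 down adjusted over the list alone, camera adjusted p = 7.01e-07, adjusted p = 0.00074 with an estimated correlation, median 0.27). In DMSO, 14 of the 23 STAT3 and STAT5 targets were already lower and 3 higher in paclitaxel-resistant than in parental cells. Whether this baseline reduced their fall was not tested. Leaving out each of the 8 libraries in turn gave 92 and 30 genes (parental DMSO replicates 1 and 2), 27 and 25 (parental ruxolitinib), 26 and 32 (resistant DMSO) and 28 and 29 (resistant ruxolitinib). The contrast followed transcript GC content across genes (Spearman rho 0.393), and GC and length correction gave 242.

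**Figure D3:**
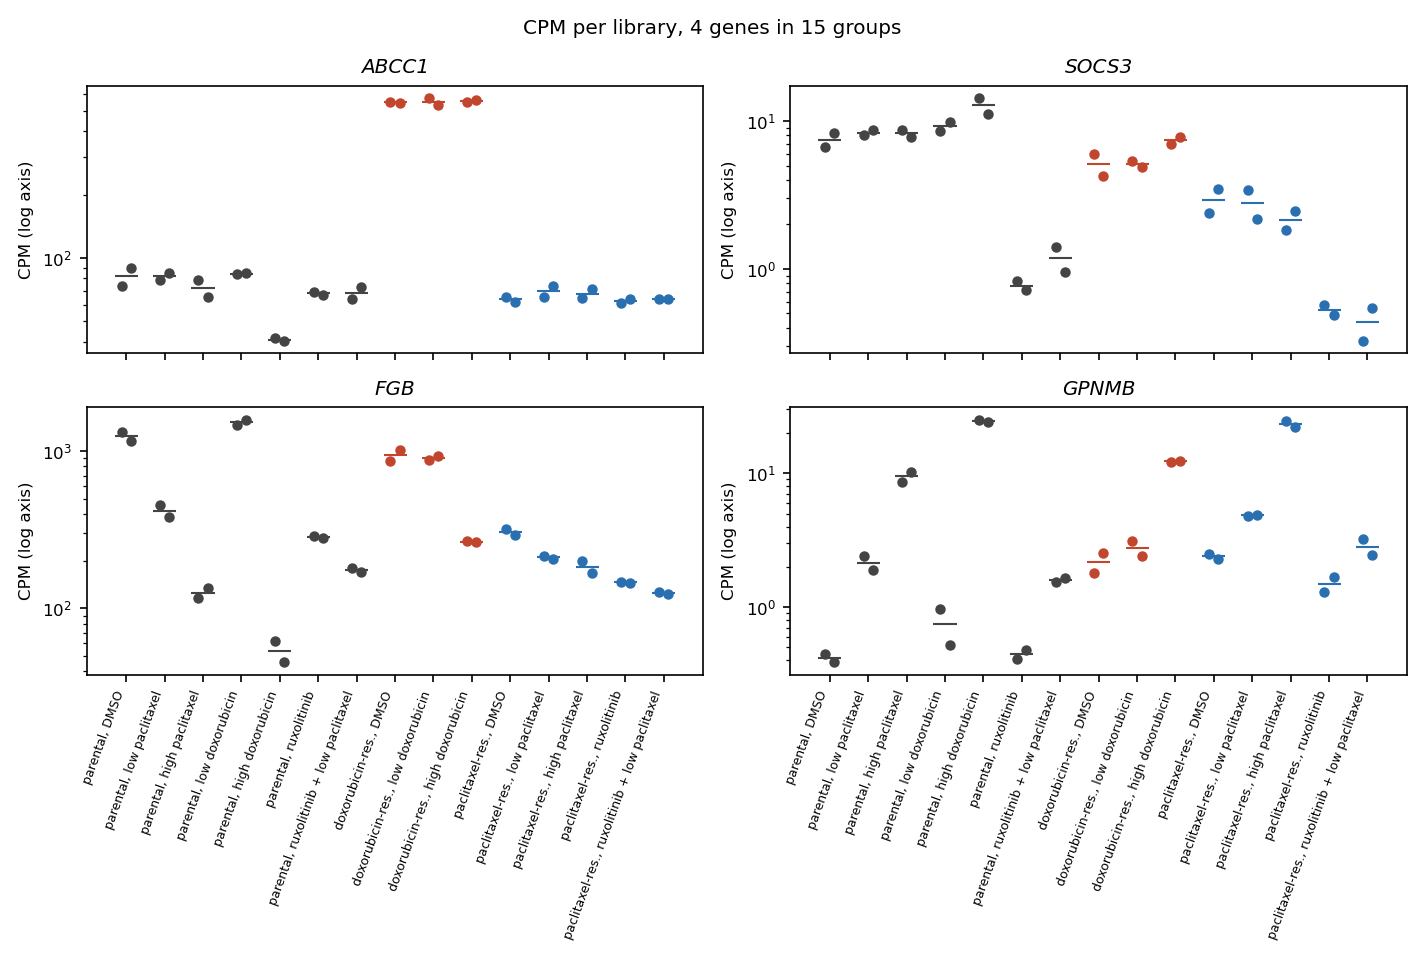
CPM per library of ABCC1, FGB, GPNMB and SOCS3 in the 15 groups on a log axis, where each point is a library, the bar is the mean of 2 and colour is the line. With ruxolitinib alone SOCS3 went from 7.48 ± 1.19 to 0.768 ± 0.0774 CPM in parental and from 2.94 ± 0.760 to 0.528 ± 0.0628 CPM in paclitaxel-resistant cells.

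Adding ruxolitinib, labelled 15 nM in these groups against 15 µM alone, to low paclitaxel asks what the inhibitor changes at a fixed paclitaxel dose. In parental cells at 2.5 nM paclitaxel, STAT3 and STAT5 targets fell for 17 of 23 (0 up and 18 down adjusted over the list alone, camera adjusted p = 5.28e-12, adjusted p = 0.019 with an estimated correlation). SOCS3 changed by -2.11 ± 0.18, SERPINA3 by -1.59 ± 0.13 and BCL3 by -1.02. Interferon-stimulated genes fell for 14 of 36 and rose for 1 (3 up and 16 down adjusted over the list alone, camera adjusted p = 3.99e-05, adjusted p = 0.0208 with an estimated correlation). IRF9 changed by -1.08. Antigen presentation genes fell for 13 of 18 (0 up and 13 down adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.0417 with an estimated correlation). NLRC5, a transactivator of class I genes, changed by -0.88. Mesenchymal genes fell for 7 of 14 (0 up and 8 down adjusted over the list alone, camera adjusted p = 4.29e-06, adjusted p = 0.0208 with an estimated correlation). TNC changed by -1.39 ± 0.12. NF-kB and cytokine genes fell for 7 of 23 and rose for 1 (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.00383, adjusted p = 0.0208 with an estimated correlation). ICAM1 changed by -1.57 ± 0.13. Genes of G2/M and mitosis rose for 20 of 30 (21 up and 0 down adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.114 with an estimated correlation). DLGAP5 changed by 0.75. In 2.5 nM paclitaxel against DMSO, which shares the paclitaxel libraries with this contrast, 21 of the 30 fell and 0 rose (camera adjusted p = 1.58e-08, adjusted p = 0.11 with an estimated correlation). HTR3A (-2.48 ± 0.13), the cadherin CDH3 (-1.64 ± 0.10), TUBB3 (-1.58 ± 0.11) and HMOX1 (-1.45 ± 0.11) fell, and SULT1E1 (1.48 ± 0.16), METTL7A (1.24 ± 0.08), ASNS (1.22 ± 0.10) and the coactivator PPARGC1A (1.05 ± 0.12) rose. After GC and length correction 3631 genes were called, of which 2448 were also called in the same direction without it. The larger direction turned with median-of-ratios scaling (1720 up and 1770 down) and with only parental libraries (687 up and 741 down). The contrast followed transcript GC content across genes (Spearman rho -0.607). It called 3561 genes, 1920 up and 1641 down, but 1025 without replicate 2 of the paclitaxel group, 736 without replicate 1 of the combination and 1428 with only parental libraries.

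In paclitaxel-resistant cells at 6.5 nM paclitaxel, with ruxolitinib again labelled 15 nM, interferon-stimulated genes fell for 12 of 36 (0 up and 21 down adjusted over the list alone, camera adjusted p = 6.06e-16, adjusted p = 0.000189 with an estimated correlation). IRF9 changed by -1.12 ± 0.15 and DTX3L by -0.70. Mesenchymal genes fell for 5 of 14 (0 up and 5 down adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.00924 with an estimated correlation). TNC changed by -1.12 ± 0.12. STAT3 and STAT5 targets fell for 5 of 23 (0 up and 5 down adjusted over the list alone, camera adjusted p = 1.63e-05, adjusted p = 0.0859 with an estimated correlation). SOCS3 changed by -1.39 ± 0.18 and the interleukin receptor IL1R1 by -0.94. Genes of the integrated stress response rose for 5 of 20 (9 up and 1 down adjusted over the list alone, camera adjusted p = 1.23e-07, adjusted p = 0.00538 with an estimated correlation). DDIT4 changed by 0.62 and ASNS by 0.61. KRT6A (-1.50 ± 0.15), CCL2 (-1.38 ± 0.19) and TUBB3 (-0.99 ± 0.11) fell, and the complement component C3 (0.89 ± 0.10), TRIM9 (0.93 ± 0.15) and the sterol transporter ABCG1 (0.78 ± 0.13) rose. In all, 418 genes were called, 148 up and 270 down. The count was 147 and 141 without paclitaxel replicates 1 and 2, 155 and 172 without combination replicates 1 and 2, 1229 after GC and length correction and 1047 with only this line.

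Across the 18 comparisons, 187 of 414 list tests passed with the preset correlation, 61 passed with both correlations and 126 with the preset one alone. Luminal epithelium genes fell for 13 of 23 and rose for 3 in parental cells at 10 nM paclitaxel (3 up and 13 down adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.17 with an estimated correlation), with the transcription factor SPDEF at -1.36; the camera adjusted p was 0.0567 without parental DMSO replicate 2. Of the 13 mitochondrially encoded genes, 1 was higher in doxorubicin-resistant than in parental cells in DMSO (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.0162, adjusted p = 0.577 with an estimated correlation). The list also passed with the preset correlation against parental DMSO in paclitaxel-resistant cells in DMSO (camera adjusted p = 0.025) and in parental cells in 10 nM paclitaxel (0.0388), 65 nM doxorubicin (0.00271) and ruxolitinib (0.000169), but in none of these with an estimated correlation. Without parental DMSO replicate 1 the camera adjusted p was 0.613, 0.669, 0.647 and 0.256 in these. In doxorubicin-resistant cells it was 0.542 without that library and 0.0761 without resistant DMSO replicate 1, and after GC and length correction the list did not pass there, in paclitaxel-resistant cells or at 10 nM paclitaxel. Against their own DMSO, paclitaxel-resistant cells in 10 nM paclitaxel passed too (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.000459, adjusted p = 0.389 with an estimated correlation).

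**Figure D4:**
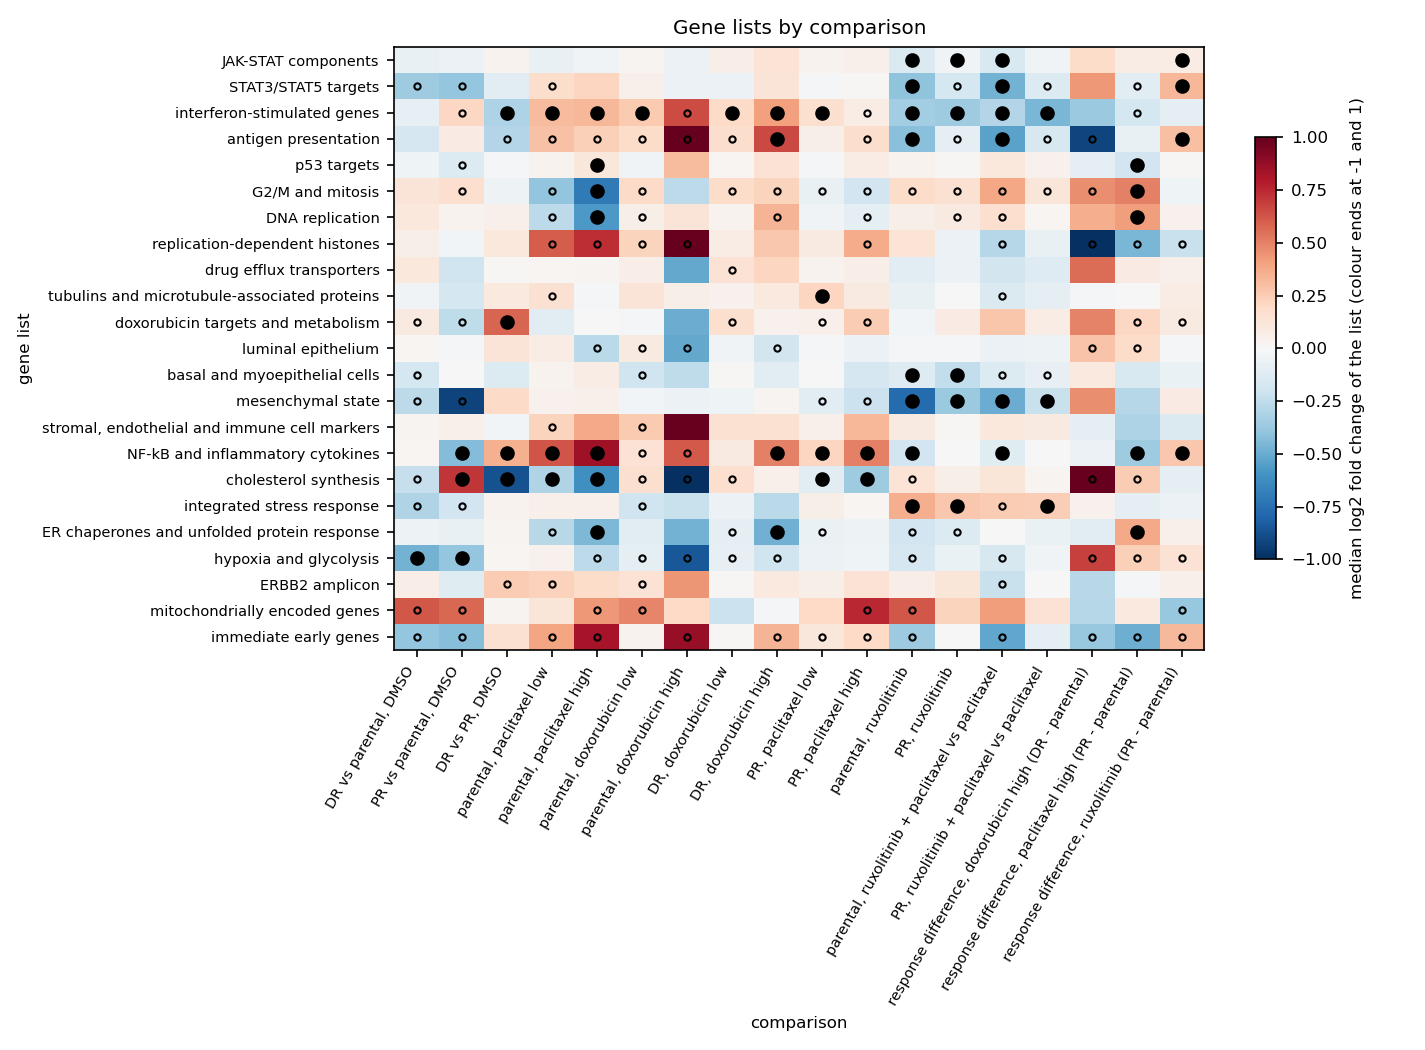
Median log2 fold change of each of the 23 gene lists in each of the 18 comparisons, where colour gives the median and a dot marks a camera adjusted p under 0.05, filled where it also passed with an estimated correlation. Of 414 list tests, 61 have a filled dot, among them cholesterol synthesis in paclitaxel-resistant cells (median 0.72) and STAT3/STAT5 targets in parental cells on ruxolitinib (median -0.40).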

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

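The tests for reads shared between duplicated genes, for a segment gain, for the dose label and for a vehicle library that lies apart were chosen after the results were seen. Those for GC content and length bias rest on a correction that was also chosen after the data were seen. The limma test of the difference between lines at the same dose drew attention to the results in the next 3 paragraphs.

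The response to 1 µM doxorubicin differed between doxorubicin-resistant and parental cells for 7434 genes, with the larger direction turning without the filter on low values (4165 higher and 4561 lower). The log2 difference was 5.32 for IGFBP5, 4.74 for CASP14 and 3.899 for the acute-phase gene ORM1. It was -4.36 for ARL14, -3.39 for the deiodinase DIO3 and -3.30 for HIST1H2AG.

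The response to 10 nM paclitaxel differed between paclitaxel-resistant and parental cells for 1370 genes, and for 639 without resistant DMSO replicate 1, 727 without resistant DMSO replicate 2 and 680 without resistant treated replicate 1. The median difference was 0.51 for genes of G2/M and mitosis, 0.42 for DNA replication, 0.38 for ER chaperones, -0.35 for NF-kB and inflammatory cytokines and -0.19 for p53 targets. It was 2.57 for FGB, 2.08 for the retinoid-responsive RARRES1, 2.003 for FGA, -1.85 for CMYA5 and -1.71 for the small GTPase GEM. ALPP (-2.02), which has a near-identical paralog, did not pass with voom.

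The response to ruxolitinib differed between paclitaxel-resistant and parental cells for 52 genes, in a contrast that followed transcript GC content (Spearman rho 0.393). The count was 92 without parental DMSO replicate 1, 30 without replicate 2, 27 and 25 without parental ruxolitinib replicates 1 and 2, 26 and 32 without resistant DMSO replicates 1 and 2, and 28 and 29 without resistant ruxolitinib replicates 1 and 2. The median difference was 0.33 for STAT3/STAT5 targets, 0.30 for antigen presentation, 0.27 for NF-kB and inflammatory cytokines and 0.072 for JAK-STAT components, the last with a camera adjusted p of 0.0827 without parental DMSO replicate 1. It was 2.01 for FGA, 1.87 for ORM1 and -1.62 for IGFBP5. HTR3A (1.72) did not pass with voom. SLC26A2 (-0.96) lost its call without any 1 of 7 libraries, all but parental DMSO replicate 1, and also without the filter and with only the lines compared. UNC5B (-0.87) lost it without parental DMSO replicate 1, either parental ruxolitinib replicate, resistant DMSO replicate 1 or resistant ruxolitinib replicate 2.

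Genes around ABCC1 on chromosome 16 were higher in doxorubicin-resistant cells, with a median log2 fold change of 0.98 over 52 genes. Only 8 of the 52 genes belonged to the duplicated families considered, and the median was 1.005 without them. The block was chosen from these same values, so this median could hardly have been low. It is therefore no separate test of reads shared between duplicated genes. After the GC and length correction the median was 0.99. This contrast followed transcript GC content and length little across genes (Spearman rho -0.061 and 0.041), so the correction could hardly move the block. Those values argue only against a GC or length trend over all genes as the cause. Gain of a chromosome segment in the resistant line is consistent with the median of 1.01 between the low-dose doxorubicin groups of both lines, which are other libraries. The highest running median over 15 genes was 1.40, and 0 of 100 shuffled gene orders reached it (highest 0.53). No shuffle reached the other highest or lowest windows examined either, such as that around SPRR1B in paclitaxel-resistant cells (-0.934, most extreme shuffle -0.566). The shuffles thus speak only against a random gene order and do not favour a segment gain. No DNA was measured, so a segment gain remains a hypothesis, and shared regulation of the region stays open as untested.

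Combinations labelled with 15 nM ruxolitinib changed many of the genes that 15 µM changed alone. The slope of the combination effect on the single-agent effect, across genes called for the single agent, was 0.722 in parental cells (Pearson r 0.882, 1685 genes) and 0.675 in paclitaxel-resistant cells (Pearson r 0.924, 882 genes). These are correlations across genes, which are not independent replicates. A combination dose written in the wrong unit is consistent with slopes this high. A 15 nM dose that already acts in these cells cannot be told apart from it: 94.1% of the genes in parental cells and 98.4% in paclitaxel-resistant cells kept their sign, which both explanations allow, and no dose series was measured.

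Low paclitaxel in parental cells gave 3414 calls along with a GC trend. Of the 1288 calls lost after correction, 74.8% had the same sign in paclitaxel-resistant cells at 10 nM, which share no library. The parental values compared were uncorrected and the resistant values corrected. Of the 2109 calls kept 92.1% did, but these were selected by the correction itself and so do not test GC content and length bias. The share for the lost calls was above the level set against such bias as the whole cause. However, no share over genes not called was computed as a baseline, so the comparison cannot decide how far bias made the calls. The number of calls was 476 without parental DMSO replicate 1 and 5172 without replicate 2, but it was also 535 without replicate 2 of the treated group. A vehicle library apart from the others therefore cannot be told apart from a treated library that lies apart, since leaving out either lowers the count by more than 1.5 times. A response to the low dose stays open for the genes called.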

How the results depend on the processing

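The voom fit, the GC and length correction and the crossed pairing of replicates were chosen only after the results were seen. The planned edgeR test on recovered reads was not run, although whole reads were recovered, and voom on those reads took its place.

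A pseudocount of 0.25 CPM, median-of-ratios scaling and replicate number as a block moved no count of called genes by more than 1.5 times. The crossed pairing, run for 3 comparisons, moved none either. Replicate numbers did not pair the groups, since the correlation of replicate differences between 105 pairs of groups ran from -0.689 to 0.65, over 0.1 in 30 and under -0.1 in 30. Without the filter 4 genes were called for 6.5 nM paclitaxel in paclitaxel-resistant cells, and with voom 5.

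With only the lines compared in the fit, the count for parental cells was 1000 in 2.5 nM paclitaxel, 461 in 65 nM doxorubicin, 775 in ruxolitinib and 1428 for the combination. For paclitaxel-resistant cells it was 114 in 6.5 nM paclitaxel, 3745 in 10 nM, 2102 in ruxolitinib and 1047 for the combination. The log2 fold changes stay the same in such a fit, so only the spread estimate and its degrees of freedom differ. Replicates differed by a median absolute log2 of 0.211 in parental DMSO and 0.058 in paclitaxel-resistant DMSO. With all lines in the fit, the same counts were higher in parental cells (3414, 1421, 1685 and 3561). They were lower in paclitaxel-resistant cells (12, 1735, 882 and 418). For ruxolitinib the line with more calls thus turned with the fit. These counts depend on which lines share a spread estimate and do not rank the lines by response. How much came from the spread and how much from its degrees of freedom was not tested.

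After GC and length correction the count was 5300 for doxorubicin-resistant against parental cells, 1681 for 350 nM doxorubicin, 2813 for 65 nM doxorubicin, 3444 and 1914 for ruxolitinib in parental and paclitaxel-resistant cells, 107 and 3572 for 6.5 and 10 nM paclitaxel in resistant cells, 1229 for their combination, and 3328 and 242 for the differences of the paclitaxel and ruxolitinib responses. The cause was not tested.

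Leaving out each library of the groups in turn gave 2280 to 3332 calls for doxorubicin-resistant against parental cells, 476 to 5172 for 2.5 nM paclitaxel, 240 to 2527 for 65 nM doxorubicin, 751 to 1727 for ruxolitinib and 736 to 3618 for the combination in parental cells. It gave 130 to 264 for 350 nM doxorubicin, and in paclitaxel-resistant cells 1 to 4 for 6.5 nM paclitaxel, 696 to 1135 for 10 nM, 358 to 407 for ruxolitinib and 141 to 172 for the combination. The differences of responses gave 639 to 1573 for paclitaxel and 25 to 92 for ruxolitinib. The other comparisons stayed within 1.5 times. A group left with 1 library is assumed to vary like the others.

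The larger direction among called genes turned in several comparisons. For 1 µM doxorubicin in parental cells it was 6778 up and 5288 down without the filter and 4848 up and 4778 down with median-of-ratios scaling. In doxorubicin-resistant cells it was 2637 up and 2419 down without the filter, 2583 up and 2389 down with that scaling and 1791 up and 1751 down without treated replicate 2. The difference of these responses was 4165 up and 4561 down without the filter. For 65 nM doxorubicin in parental cells it was 724 up and 665 down with that scaling, 266 up and 195 down with only parental libraries and 137 up and 103 down without treated replicate 2. For 10 nM paclitaxel in paclitaxel-resistant cells it was 908 up and 820 down without the filter, 377 up and 335 down without DMSO replicate 1, and 528 up and 515 down and 608 up and 527 down without treated replicates 1 and 2. For the combination in parental cells it was 1720 up and 1770 down with that scaling, 687 up and 741 down with only parental libraries, 457 up and 568 down without replicate 2 of 2.5 nM paclitaxel and 363 up and 373 down without replicate 1 of the combination. For paclitaxel-resistant against parental cells, with 2078 up and 2076 down, it was 2060 and 2083 with the smaller pseudocount, 2009 and 2011 with a replicate block, 2855 and 3045 after GC and length correction and 2055 and 2262 without parental DMSO replicate 1. The cause was not tested.

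Of 414 list tests, 126 lost their call with an estimated correlation. With fry 24 lost and 72 gained a call, with the GC and length correction 23 and 17, with voom 3 and 5, with median-of-ratios scaling 5 and 5, without the filter 8 and 18, with the lower pseudocount 2 and 5, with only the lines compared 3 and 9, and with the block 0 and 2. Over the leave-one-out fits, each list test was counted for each library left out, so 1 test can count repeatedly. A call was lost 79 times and gained 60 times, and a direction reversed 2 times. The mitochondrially encoded genes in the difference of ruxolitinib responses ran from a median of -0.83 to 0.105, the latter without parental DMSO replicate 1. Replication-dependent histones for the combination in parental cells ran from -0.65 to 0.112, the latter without replicate 2 of 2.5 nM paclitaxel. Neither list passed in the fit where it reversed. The cause was not tested.

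Of 312 results for named genes, none changed direction under these alternatives. The calls of ALPP and HTR3A in the differences of responses ended with voom, those of SLC26A2 and UNC5B ended without single libraries, SLC26A2 also without the filter and with only the lines compared, and ERBB2 between the resistant lines gained a call after GC and length correction.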

Other observations

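All values in this part were chosen after the data were seen. In paclitaxel-resistant cells, 55 of 62 tested genes from PIGA to KDM6A on the X chromosome were higher than in parental cells and 0 were lower by limma, with a median log2 fold change of 0.58 (0.45 in doxorubicin-resistant cells). The ends of this run were set by running medians of at least 0.5 in the same comparison, so a high share was built in. Of all 12743 tested genes, 2078 were higher. Both resistant lines were compared with the same parental DMSO libraries, so a difference of the parental line cannot be told apart. The lowest running median over 15 genes lay on chromosome 1 around SPRR1B for paclitaxel-resistant against parental cells (-0.93). For doxorubicin-resistant against parental cells it lay on chromosome 12 around SDSL (-0.66). For the resistant lines against each other it lay on chromosome 16 around SHCBP1 (-1.01).

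Across genes called in parental cells, the slope of the resistant on the parental response was 0.583 for ruxolitinib (Pearson r 0.835), 0.416 for 10 nM paclitaxel and 0.258 for 1 µM doxorubicin. Among genes called in the resistant line it was 0.821, 0.608 and 0.379. The slopes thus changed with the genes selected, and spread in the parental change they are fitted on lowers them. They do not measure how much weaker the resistant response was.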
